A study of Mus musculus with 29 samples.

How the data were processed

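The series profiles protein binding and histone acetylation on chromatin by ChIP-seq in a pair of mouse tumour cell lines: AT-3, a mammary carcinoma line, and Eμ-Myc, a B-cell lymphoma driven by a Myc transgene, whose line is numbered #1 in the labels. Of 29 samples, 26 carry a peak list and were used; the other 3 are input libraries, which entered only through the authors' peak calling and were not used here. AT-3 cells were profiled with antibodies against RNA polymerase II, BRD4, H3K27ac (an acetylation mark of active promoters and enhancers), IRF1 and STAT1, each under 4 treatments: DMSO vehicle, the BET bromodomain inhibitor JQ1 at 1000 nM, interferon-γ (IFN-γ) at 1 ng/mL, and both together. Eμ-Myc cells were profiled for BRD4, RNA polymerase II and MYC with DMSO or 1000 nM JQ1. The sample titles call the controls untreated while the treatment field says DMSO; they are called DMSO here. A JQ1 exposure of 2 h is stated for the Eμ-Myc BRD4 and RNA polymerase II libraries; the exposure of the other libraries was not given in the sources used here. Library kits differed: per the labels' protocols, the MYC libraries were prepared with another kit than all the rest.

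Reads were processed with CASAVA 1.8.2, Bowtie2 2.2.3 and MACS2 on the GRCm38/mm10 build, per the submitters' processing notes. Peaks were called for each library on its own against an input library, not on pooled samples, per the file headers. The AT-3 lists came from MACS2 2.1.1.20160309 and the Eμ-Myc lists from MACS2 2.0.10.20130306, both with an effective genome size of 1.87e+09, at most 1 tag kept per position, the larger dataset scaled towards the smaller and local background windows of 1000 and 10000 bp. All 20 AT-3 libraries share an input of 13.2 M tags after filtering; the Eμ-Myc BRD4 and RNA polymerase II libraries share an input of 14.3 M and the MYC libraries an input of 46.3 M. The threshold was q 0.05 for AT-3 BRD4, H3K27ac, IRF1 and RNA polymerase II and for MYC. It was p 0.01 for the AT-3 STAT1 lists and the Eμ-Myc BRD4 and RNA polymerase II lists, so those lists hold many weak peaks and their lengths are compared within an antibody and cell line only. Each list gives the position of a peak and of its summit, the pileup signal at the summit, that is the coverage by extended tags, as the authors deposited it, the −log10 of the p-value and of the q-value as the authors' caller wrote them, and the fold enrichment, a ratio over the local background computed by the authors. The Eμ-Myc BRD4 and RNA polymerase II lists have no usable q-value: the score in that column is a placeholder in the deposited files, and −log10 p was used in its place. The STAT1 lists have a filled q column although a header line says that q was not calculated, so their q values, used as written, are in doubt. The remaining deposited columns hold coordinates, lengths and peak names, other values that the authors' caller wrote. Fold enrichment is the authors' own value throughout, and was used to describe, rank or filter peaks, and to bin and match peaks or gene regions.

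Depth was read from the headers as the tags, in megatags (M), of each ChIP library after duplicate filtering. It ran from 9.43 to 23.6 M in AT-3 and from 11.8 to 33.7 M in Eμ-Myc. Shares of peaks are given with 95% Wilson intervals. These cover counting error only, since there was 1 library per group and no replicate of any treatment. No difference between treatments therefore has a replicate check, and no p-value was computed. Peak lists were compared with bedtools 2.31.1, counting a peak as shared at an overlap of at least 1 bp, in both directions. The comparisons were JQ1 with DMSO, IFN-γ with DMSO, JQ1 plus IFN-γ with IFN-γ, and JQ1 plus IFN-γ with JQ1 for each of the 5 AT-3 antibodies, and JQ1 with DMSO for each of the 3 Eμ-Myc antibodies, 23 in all.

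Genes came from a table of 21883 protein-coding genes of GRCm38 that gives the outermost start and end of a gene without strand, exons or start sites. A gene region was taken as the gene and 1 kb either side; the design had foreseen 1 kb around start sites, which this table cannot give, and the outermost ends of some genes lie far from their main promoter. A peak shared by neighbours counts for each of them. A region was gained or lost when it held a peak in only the second or only the first list, and firmly so when that peak had −log10 q (p where no q exists) of at least 10 and the other list held no peak at all in the region. A firm call can still come from the edge of a peak that the other list holds beside the region: this was so for 0.776% of firm BRD4 losses with JQ1 in AT-3 cells and for 26.5% of firm polymerase losses. Such calls, found after the results were seen, stay in the counts; where named, the text says so, and the other firm calls named met no peak of the other list. The 18 gene lists, of 14 to 30 genes each, were: the PD-L1 locus and other checkpoint ligands, IFN-γ signalling and IRF/STAT regulators, MHC class I and antigen processing, interferon-inducible GTPases, interferon-inducible chemokines and cytokines, antiviral interferon-stimulated genes, BET-inhibitor-sensitive regulators, MYC targets, immediate early and stress genes, NF-κB and inflammatory genes, cell cycle and replication genes, apoptosis regulators, core histones, housekeeping genes, B-lineage genes, epithelial and mammary tumour genes, markers of other cell types, and silent tissue-specific genes as a background. 4 symbols had no gene in the table (Hhla2, Cxcl11, Mx1 and Mx2). The number of members lost was set beside 10000 random lists of the same size matched on 10 bins of fold enrichment in the first list, and the number gained beside random lists matched on H3K27ac and RNA polymerase II occupancy in DMSO (polymerase alone in Eμ-Myc). The percentile describes these libraries, with 828 percentiles computed in all; genes are not replicates.

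Genes named in the text follow a rule fixed, like the designs and most alternatives, before the data were examined: Cd274 throughout, 2 to 4 members per list and comparison by highest fold among the gained and lost members, and up to 10 firm gains and 10 firm losses per comparison with the highest fold, no more than 1 per Mb of chromosome and without model names; where a count is 5 or fewer, all are named. Where a gene outside that rule is named, the text says so. IRF1, STAT1 and MYC peaks were set against BRD4, H3K27ac and polymerase peaks of the same treatment, with 100 shuffles of the peaks on their own chromosome as the level given by chance. Losses or gains seen in a pair of comparisons that share no library were counted beside the overlap that independent lists would give and, added after the results were seen, that of lists matched on 10 bins of fold in each reference (losses) or on 10 bins of gene length and on polymerase and H3K27ac occupancy with DMSO (gains). Alternatives were a stricter threshold, an overlap of 50% of the shorter peak, lists of equal length, flanks of 2.5 kb, gene ends alone, the STAT1 lists at q 0.05, and AT-3 lists without recurrent regions, those listed in at least 7 of the 8 IRF1 and STAT1 lists; motifs were not run, since no genome sequence was used here. The code was tested on simulated peak lists for 3400 genes, 3000 of them occupied in both lists: 200 of 200 made losses and 200 of 200 made gains were recovered, with 0 false calls. These genes had flanks that met no other gene and a single peak at their middle. Calls from shared peaks or peak edges could therefore not arise in the test. For all 23 comparisons the overlap counts equalled those of bedtools. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.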

Results

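ChIP-seq peak lists were examined for 26 libraries, 1 per antibody, cell line and treatment. The AT-3 mammary carcinoma line contributed 20 lists from 5 antibodies and the Eμ-Myc lymphoma line 6 lists from 3. JQ1 displaces BRD4, a reader of acetylated histones, from chromatin, and IFN-γ is a cytokine that raises expression of PD-L1, the checkpoint ligand encoded by Cd274 and named in the title of the series. The comparisons therefore ask how JQ1 alters the occupancy of BRD4, RNA polymerase II, H3K27ac and transcription factors at Cd274 and elsewhere, with and without IFN-γ. In AT-3 cells the ChIP libraries held 9.43 to 23.6 M filtered tags and 684 to 70960 peaks. Those of Eμ-Myc cells held 11.8 to 33.7 M tags and 21491 to 139902 peaks. As each group had a single library, no difference reported has a replicate check, and the intervals given cover counting error only.

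**Figure D1:**
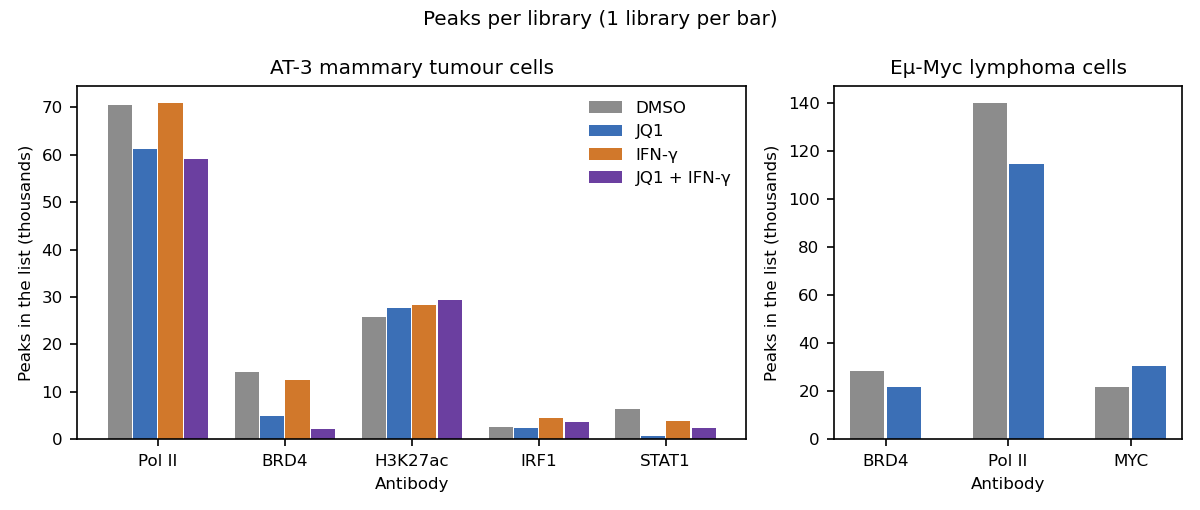
Number of peaks in each list (y axis, in units of 1000) by antibody (x axis), for AT-3 cells on the left and Eμ-Myc cells on the right; each bar is 1 library and its colour gives the treatment, with no error bars because there were no replicates. AT-3 BRD4 peaks numbered 14055 with DMSO, 4803 with JQ1, 12384 with IFN-γ and 2144 with both, while MYC peaks in Eμ-Myc cells numbered 21790 with DMSO and 30532 with JQ1.

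At Cd274 in AT-3 cells, BRD4 and H3K27ac peaks were listed only in the libraries that received IFN-γ. JQ1 added to IFN-γ left the H3K27ac and IRF1 peaks in place, while the BRD4 signal shrank to a single short peak and the polymerase domain over the gene was broken up. Cd274 lies on chromosome 19 at 29362107 to 29388095 (GRCm38, 26.0 kb), and its first part overlaps the neighbouring Plgrkt gene, which ends at 29367292. No exon or strand information was used, so peaks are described only as over the gene or beside it. With IFN-γ, the main BRD4 peak spanned 29366061 to 29368465 (2405 bp, fold enrichment 14.8), with 2 weaker ones beside it. With JQ1 and IFN-γ together, BRD4 was reduced to a peak of 265 bp at 29367341 to 29367605 (fold 3.92). The main H3K27ac peak spanned 29365358 to 29368037 with IFN-γ (fold 17.5) and 29365722 to 29368037 with both agents (fold 16.5). IRF1, a transcription factor induced by IFN-γ, already had a peak at this site in DMSO (fold 6.75) and JQ1 (fold 7.45). Its fold was 34.9 with IFN-γ and 26.4 with both, and a second IRF1 peak appeared at 29371782 to 29372264 with IFN-γ (fold 16.2) and at 29371781 to 29372322 with both (fold 14.2). RNA polymerase II formed a continuous domain of 26129 bp over the gene with IFN-γ, from 29365662 to 29391790 (fold 22.4). With JQ1 as well, the strongest peak covered 4109 bp at 29366018 to 29370126 (fold 20.3), and 16 separate peaks lay over the gene and 1 kb either side. In DMSO there were 2 weak polymerase peaks at the lower-coordinate end of the gene (folds 4.67 and 3.25), and with JQ1 1 (fold 4.45) beside the gene. None of the 4 STAT1 lists held a peak at Cd274 or within 20 kb of it. In Eμ-Myc cells a weak BRD4 peak at 29367506 to 29367661 (fold 3.91) was listed with DMSO and none over the gene with JQ1. MYC occupied the same site in both lymphoma libraries (fold 10.8 with DMSO and 14.1 with JQ1), as did polymerase (fold 6.37 and 7.72).

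**Figure D2:**
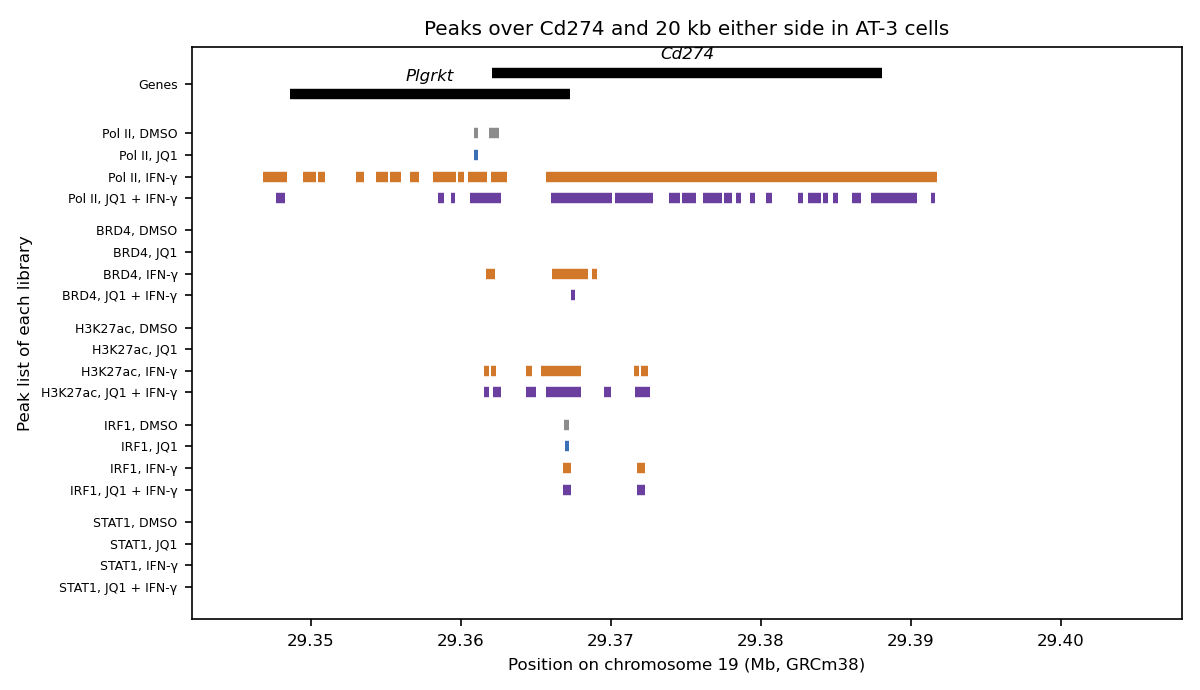
Peaks called in each AT-3 library (y axis) over Cd274 and 20 kb either side, by position on chromosome 19 (x axis, Mb, GRCm38); black bars are gene extents, coloured bars are peaks and colour gives the treatment. BRD4 and H3K27ac peaks appear only with IFN-γ, and the polymerase domain of 26129 bp seen with IFN-γ is replaced by separate peaks, the strongest of 4109 bp, when JQ1 is added.

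IFN-γ alone was compared with DMSO in AT-3 cells to find where the cytokine brings BRD4, polymerase, acetylation and its transcription factors. BRD4 appeared over interferon-responsive genes of every class examined while its total number of occupied genes changed little. All 28 antiviral genes, 16 GTPases and 18 MHC class I genes carried BRD4 with IFN-γ, against 19, 9 and 11 with DMSO. Among the antiviral genes, 9 gained BRD4 (random mean 1.46, percentile 100), led by Herc6 (fold 14.8), Oas2 (14.3), which encodes a sensor of viral RNA, and Samd9l (11.9). Of the interferon-inducible GTPases, which attack vacuoles of intracellular pathogens, 7 gained it (random mean 0.329, percentile 100), with Tgtp2 (23.3), Iigp1 (20.3) and Gbp5 (19.3) highest. The MHC class I and antigen processing list gained 7 (random mean 1.30, percentile 100), led by the peptide transporter subunit Tap2 (11.9) and the immunoproteasome subunit Psmb8 (11.3). Chemokines and cytokines went from 5 to 12 of 15 (7 gained, random mean 0.960, percentile 100), including the T-cell attractants Cxcl10 (30.6) and Cxcl9 (22.2). In the list of IFN-γ signalling genes, 4 were gained (random mean 0.797, percentile 99.9): Batf2 (8.54), Irf8 (7.77), Ifi35 (5.69) and Ciita (4.81), the master regulator of MHC class II. Checkpoint ligands gained Cd274 (14.8), Cd86 (7.64) and Lgals9 (6.80) and lost Pvr (6.05), Nectin2 (5.31) and Vsir (4.99), so that 7 of 14 were occupied in either library. Outside the lists, firm BRD4 gains included Slfn1 (21.4), Sectm1a (16.6) and Samhd1 (16.1), and firm losses included Ano2 (37.6), Myo7a (26.1) and Marchf1 (19.5). In total 7782 gene regions carried BRD4 with DMSO and 7105 with IFN-γ, with 1601 lost (145 firmly) and 924 gained (153 firmly). Of the DMSO peaks, 60.1% (95% interval 59.3 to 60.9) were overlapped by IFN-γ peaks.

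Among the interferon lists, GTPases gained the most members with polymerase and H3K27ac under IFN-γ, while most genes of the other lists already carried a peak of them with DMSO. For polymerase, 18 of 18 MHC class I genes did so, 26 of 28 antiviral genes (28 with IFN-γ) and 11 of 15 chemokines and cytokines (13 with IFN-γ). For H3K27ac the counts with DMSO were 17, 26 and 9, and with IFN-γ 18, 28 and 11. A peak of any length counts, and the length under polymerase peaks, examined after the results were seen, rose in these lists too. The median went from 19.9% to 94.8% for 24 antiviral genes (22 higher, 0 lower). For 15 MHC class I genes it went from 63.9% to 100% (9 higher, 2 lower), and for 19 IFN-γ signalling genes from 10.3% to 94.6% (16 higher, 2 lower). RNA polymerase II went from 10 to 16 of 16 GTPases (6 gained, random mean 0.453, percentile 100; Gbp6 at 88.1 and Tgtp2 at 81.7), and H3K27ac also went from 10 to 16 (6 gained, random mean 0.285, percentile 100; Gbp5 at 15.8 and Gbp9 at 13.4). Polymerase also appeared at Cxcl9 (108) and Ccl7 (9.95), at Batf2 (12.3), Ciita (7.37) and Irf8 (6.14), and at the antiviral genes Trim21 (20.5) and Rsad2 (12.9). Acetylation appeared at Cxcl10 (12.7), Cxcl9 (9.51), Oas3 (14.0), Rsad2 (8.25), Psmb8 (19.3), Cd274 (17.5) and Cd86 (5.26). Outside the lists, firm gains whose peak met none of the DMSO list included Trim12c (35.7) and Snx10 (31.3) for polymerase, and both also for H3K27ac (19.6 and 19.8). The polymerase peaks reaching Gbp2b (146) and Tnp2 (86.6) were not new, since their neighbours Gbp2 and Socs1, a feedback inhibitor of cytokine signalling, already carried polymerase with DMSO. Across all genes the lists were stable: 12130 gene regions carried polymerase with DMSO and 12076 with IFN-γ (492 lost, 438 gained), and 11186 and 11297 carried H3K27ac (358 lost, 469 gained). Firm calls leaned to gains, 117 against 25 for polymerase and 143 against 36 for H3K27ac. The net change was small enough to change sign with the settings: for polymerase it was −54 and became 199 among strong peaks, and for H3K27ac it was 111 and became −34 when peaks counted only near gene ends. Of DMSO peaks, 62.7% (62.4 to 63.1) for polymerase and 80.3% (79.9 to 80.8) for H3K27ac were overlapped with IFN-γ.

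IRF1 moved to a largely different set of sites with IFN-γ. The list grew from 2484 to 4509 peaks, and 3427 of the latter overlapped no DMSO peak. IRF1 occupied 24 of 28 antiviral genes against 8 with DMSO (16 gained, random mean 1.69, percentile 100), led by Ifit1 (32.9), which binds viral RNA, and Oasl2 (30.4). It gained 10 GTPases (random mean 0.810, percentile 100; Gbp2 at 34.1, Ifi47 at 25.5) and 10 MHC class I genes (random mean 0.965, percentile 100; Psmb10 at 38.2, Tapbpl at 28.1), and none of either list was lost. The IFN-γ signalling list gained 7 (random mean 1.25, percentile 100; Nlrc5, the transactivator of MHC class I genes, at 26.1) and lost Socs3 (6.99). Cd274 carried IRF1 in both libraries, and the other checkpoint ligands Cd86 (15.3), Cd47 (7.18) and Tnfrsf14 (6.54) gained it. The strongest firm gains lay over genes outside the lists, such as Msi2 (122), Rdx (120), Dpysl3 (108) and Rabgap1l (108); firm losses included Iffo2 (16.7) and Arhgef1 (16.0). Of gene regions, 800 were lost and 1293 gained (289 and 961 firmly), from 1495 to 1988 in total. That net gain of 493 turned to −160 when only peaks within 1 kb of a gene end counted and to −416 with lists of equal length.

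STAT1, the transcription factor activated directly by the IFN-γ receptor, was called at a more lenient threshold, and its lists hold many weak peaks. With IFN-γ it was gained at 9 of the 16 GTPases (random mean 0.975, percentile 100; Iigp1 at 8.58, Gbp2 at 6.69, Tgtp1 at 5.69; Gvin1 at 3.04 lost), at 7 antiviral genes (random mean 1.83, percentile 99.9; Isg15 at 4.38, Ifit1 at 4.23; Herc6 at 2.66 and Dhx58 at 2.46 lost), at 5 IFN-γ signalling genes (random mean 1.19, percentile 99.8; Parp14 at 4.12, Irf7 at 3.51, Irf9 and Stat2 at 3.18, Stat1 at 2.87) and at Cxcl10 (5.45), Cxcl9 (3.81) and Tnfsf10 (3.80). The IFN-γ signalling list also lost Pias1 and Stat3 (3.80) and Irf2 (3.42), and the chemokines and cytokines lost Cxcl1 (4.03), Cx3cl1 (3.04) and Cxcl5 (2.65), which left 3 of 15 with STAT1 in either library. Even so, the list was shorter with IFN-γ (3786 peaks) than with DMSO (6357), and gene regions went from 3130 to 1882, with 2226 lost and 978 gained. The firm gains were Kcnip4 (9.76), Ube2cbp (9.13), Iigp1, Abcb1a (8.19), Pcdh15 (7.85) and Sfmbt2 (7.56), and the firm loss was Cebpb (9.09). None of the markers of other cell types (T, myeloid, endothelial, fibroblast) gained a STAT1 peak. Of the DMSO peaks, 14.7% (13.8 to 15.6) were overlapped by IFN-γ peaks. That share was 48.0% at q 0.05, where the net change of −1248 gene regions was −64; among strong peaks it was 11.

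**Figure D3:**
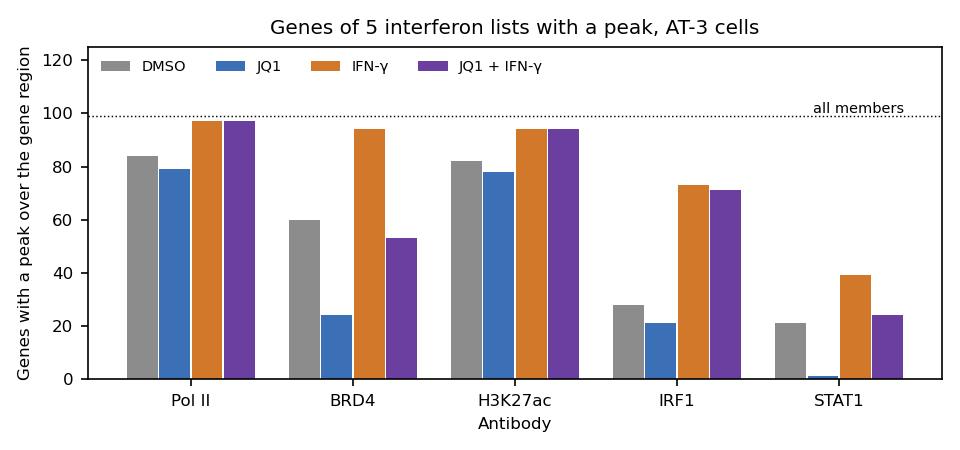
Number of the 99 genes of the 5 interferon lists with a peak over the gene or within 1 kb (y axis) for each AT-3 antibody (x axis); each bar is 1 library, colour gives the treatment and the dotted line marks all members. With JQ1 and IFN-γ together, 97 carried polymerase and 94 H3K27ac, as with IFN-γ alone, while 53 carried BRD4 against 94.

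JQ1 alone was compared with DMSO to find which sites lose BRD4 and what else changes there. Most BRD4 peaks of AT-3 cells were missing from the JQ1 list, while polymerase and H3K27ac stayed over nearly all the same genes. BRD4 occupied 3474 gene regions with JQ1 against 7782 with DMSO, with 4394 lost (1031 firmly) and 86 gained. The sole firm gain, Btn1a1 (9.07), a butyrophilin of the milk fat globule, was a peak that the DMSO list also held in part, outside the gene region. Of the 1031 firm losses, 997 carried polymerase with DMSO and 984 with JQ1, and 996 and 977 carried H3K27ac. Cell cycle and replication genes lost BRD4 at 12 of 16 (random mean 8.79, percentile 96.0), with cyclin E2 gene Ccne2 (11.9), E2f2 (10.7) and Ccna2 (8.40) highest. Checkpoint ligands went from 7 to 1 of 14 (6 lost, random mean 4.35, percentile 92.0; Cd276 at 10.6, Vtcn1 at 7.00). IFN-γ signalling genes went from 16 to 6 (10 lost, random mean 9.11, percentile 68.0; Stat1 at 10.4, Irf9 at 8.40), GTPases from 9 to 2, antiviral genes from 19 to 9 and MHC class I genes from 11 to 5, each near its random mean. The same held for BET-inhibitor-sensitive regulators (5 of 16 lost, random mean 5.02; Cdk6 at 10.3, Bcl2 at 9.71, Pim1 at 7.32, Ccnt1 at 5.77, and Fosl1 at 4.94 by the edge of a peak that stayed) and MYC targets (10 of 24 lost, random mean 10.3; nucleolin gene Ncl at 10.7, Wdr43 at 9.73), at percentiles 49.8 and 43.2. Immediate early and stress genes stood at the other extreme: only Btg2 (7.08) of 15 lost BRD4 (random mean 5.68, percentile 0.0900). Smaller lists lost 5 of 12 apoptosis regulators (Bad at 9.23, Xiap at 7.52, Bid at 6.63, Apaf1 at 5.75, Fas at 3.63), 3 of 9 NF-κB genes (Birc3 at 6.63, Tnfaip3 at 6.59, Nfkb2 at 3.03), 6 of 16 epithelial genes (Krt7 at 10.8, Erbb2 at 10.2) and 3 of 19 housekeeping genes (Rps3 at 9.87, Tbp at 7.08, Sdha at 5.17). The B-lineage genes Cd79a (5.03, by the edge of a peak that stayed) and Rag2 (4.42), the fibroblast marker Pdgfra (6.19) and Tnnt2 (8.24), listed as a silent tissue-specific gene but carrying polymerase in these cells, also lost their peak. Outside the lists the strongest firm losses were Ano2 (37.6), Myo7a (26.1), Marchf1 (19.5) and the splicing factor gene Sf1 (19.3). The peaks over the first 3 were missing from the IFN-γ list too, so the same peaks of the shared DMSO library count as losses in both comparisons. The JQ1 list kept 29.4% (28.6 to 30.1) of DMSO peaks, and 93.8% (93.1 to 94.4) of JQ1 peaks were already in the DMSO list. With lists of equal length 60.6% were shared, the net change was −83 gene regions, and antiviral, apoptosis, housekeeping, MHC class I and NF-κB genes had a net gain of 1 or 2.

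The other AT-3 antibodies changed less with JQ1, apart from STAT1. Polymerase went from 12130 to 11783 gene regions (604 lost, 257 gained, of these 49 and 23 firmly) and H3K27ac from 11186 to 10747 (655 lost, 216 gained, of these 148 and 7 firmly). Among strong peaks the net change was −194 instead of −347 for polymerase and −1019 instead of −439 for H3K27ac. Polymerase was lost from Psmb8 (5.75) and Tap2 (5.06), from the chemokine genes Ccl2 (6.87) and Cxcl10 (4.00), and from Dhx58 (7.00), Casp9 (6.87) and Egr3 (6.50); firm losses whose peak met none of the JQ1 list were led by Oacyl (10.5) and Dnph1 (10.3). H3K27ac was lost from Ccne1 (9.88) and Tap2 (7.04), while the regions of Polr1b (16.8), Fosl1 (14.0) and Tnp2 (23.5) lost only the edge of a peak that stayed. IRF1 went from 1495 to 1138 gene regions (619 lost, 262 gained) and lost Psmb8 and Tap1 (7.32, a shared peak), Tnfsf10 (7.32) and Stat1 (6.76). The STAT1 list shrank from 6357 to 684 peaks, and gene regions from 3130 to 330. STAT1 was lost from the keratin gene Krt5 (20.0) and firmly also from Eapp (10.2), Krt17 (8.74) and Tmpo (8.46), while core histone genes kept it at 11 of 16 (lost H4c4 at 4.92, H2az1 at 4.56, H1f5 at 4.49, H2ac6 and H2bc4 at 4.06; random mean 10.9, percentile 0.0700). With STAT1 lists of equal length the net change was 2 gene regions instead of −2800. Of DMSO peaks, JQ1 kept 57.2% (56.9 to 57.6) for polymerase, 81.1% (80.6 to 81.6) for H3K27ac, 63.1% (61.2 to 65.0) for IRF1 and 6.04% (5.48 to 6.65) for STAT1. The STAT1 share was 34.2% among strong peaks, 41.96% with lists of equal length and 20.6% at q 0.05.

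With JQ1 added to IFN-γ, most BRD4 peaks of AT-3 cells were missing, while polymerase, H3K27ac and IRF1 remained over nearly all interferon-responsive genes that carried them with IFN-γ. BRD4 went from 7105 to 1504 gene regions, with 5616 lost (1594 firmly) and 15 gained; the firm gains were Gys1 (10.5) and Gcat (9.06, the edge of a peak also listed with IFN-γ). It remained over 17 of 28 antiviral genes (lost Ddx58, the viral RNA sensor, at 15.5, Herc6 at 14.8 and Oas2 at 14.3), 13 of 16 GTPases (lost Gbp4 at 11.0, Gvin1 at 6.35 and Gbp8 at 5.40) and 11 of 18 MHC class I genes (lost Tap2 at 11.9, Psme2 at 8.54). Losses of MHC class I genes were fewer than in matched random lists (7, random mean 10.2, percentile 3.54). Chemokines and cytokines went from 12 to 3 (9 lost, random mean 7.34, percentile 88.5; Il18bp at 11.9, Il15ra at 10.4), and all 15 cell cycle genes with BRD4 lost it (Cdk1 at 9.09, Ccne2 at 7.18). MYC targets went from 27 to 10 (Ncl at 11.8, Odc1 at 8.07), BET-inhibitor-sensitive regulators from 18 to 9 (random mean of losses 12.4, percentile 1.49; Bcl2l1 at 8.05), and immediate early genes from 14 to 11 (random mean of losses 8.31, percentile 0.0200; Hspa1b at 7.77, Btg2 at 5.40, Dusp1 at 3.74). Outside the lists, firm losses whose peak met none of the other list were led by Ube2a (37.8), Slfn1 (21.4) and Tbkbp1 (21.1). Of the 924 gene regions that had gained BRD4 with IFN-γ, 43 carried it when JQ1 was present, 808 carried polymerase (841 with IFN-γ alone) and 840 H3K27ac (852 with IFN-γ alone). Most of these regions were occupied before IFN-γ, as 725 carried polymerase and 728 H3K27ac with DMSO. Among the 153 firm BRD4 gains, 39 carried BRD4 with both agents. Only 13.8% (13.2 to 14.4) of IFN-γ BRD4 peaks were overlapped in the combination, against 54.9% (54.5 to 55.3) for polymerase and 70.3% (69.0 to 71.6) for IRF1; of H3K27ac peaks with both agents, 80.4% (79.95 to 80.9) lay in the IFN-γ list. With lists of equal length the BRD4 share was 53.8%, the net change −290 gene regions, and epithelial, immediate early, MYC target and NF-κB genes had a net gain of 1 to 4.

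Among the other antibodies in this comparison, polymerase and H3K27ac lost no member of the antiviral, GTPase, MHC class I, chemokine or IFN-γ signalling lists. A member counts as kept with any peak left in its region. Of 76 interferon-list genes with polymerase in all 4 AT-3 lists, 41 had less of their length under polymerase peaks with both agents and 7 more. Over all 10719 genes with polymerase in these lists, 6333 had less and 3846 more, so a drop was not particular to interferon genes. With IFN-γ the 76 genes had a median of 98.6% of their length covered, close to the ceiling of 100%. For polymerase 554 gene regions were lost and 328 gained (71 and 27 firmly), and the firm losses whose peak met none of the other list were led by Mgam (17.0) and Hcn1 (11.2). H3K27ac lost 631 and gained 271 (154 and 17 firmly), among them the inflammatory genes Tnf (6.99) and Relb (5.26); its firm losses of that kind were led by Pqbp1 (14.2) and Elmod2 (12.7). IRF1 kept 23 of 24 antiviral genes, losing only Oas1a (7.18; random mean 3.55, percentile 2.35), and all 14 GTPases and 17 MHC class I genes, while Cxcl10 (3.62) was lost from the chemokines. Of all gene regions with IRF1, 586 were lost and 141 gained. STAT1 went from 1882 to 1229 gene regions with no firm gain; it lost Ifit1 (4.23) and Oasl2 (3.51) among 8 of 11 antiviral genes (random mean 8.19), and firmly Tmc1 (9.76), Il1rapl1 (8.19) and Cdk15 (6.97). With STAT1 lists of equal length the net change was 161 instead of −653.

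IFN-γ was also compared in the presence of JQ1, as the combination against JQ1 alone. Members of the interferon lists gained each of the 5 marks although the BRD4 list as a whole was shorter with both agents than with JQ1. BRD4 was gained at 11 GTPases (2 to 13 of 16, random mean 0.192, percentile 100; Gbp2 at 27.8, Igtp at 18.4), at 9 MHC class I genes (random mean 0.299, percentile 100; Psmb9 and Tap1 at 9.06, a shared peak) and at 9 antiviral genes (random mean 0.409, percentile 100; Ifit1 at 8.86, Ifit3 at 8.57). It was also gained at Stat1 (8.00), Nlrc5 (6.39), Nmi (5.20) and Parp14 (5.02), and at Cd274 (3.92). Chemokines and cytokines went from 2 to 3 of 15, with Tnfsf10 (8.73), Cxcl9 (6.05) and Cxcl10 (5.55) gained and Cxcl1 (6.42) and Cxcl5 (5.65) lost. Members of the same lists lost were Calr (7.27), Canx (5.07) and Pdia3 (3.66) of the MHC class I list, Ddx58 (5.47) and Stat3 (4.77). At the same time BRD4 gene regions went from 3474 to 1504, with 2171 lost and 201 gained (309 and 33 firmly), and the stem-cell antigen gene Ly6a (9.40) was a firm gain. With BRD4 lists of equal length the net change was −200 gene regions instead of −1970, and 54.3% of JQ1 peaks were shared. Polymerase was gained at 7 GTPases (random mean 0.582, percentile 100; Gbp6 at 64.3), at Cxcl10 (86.9), Cxcl9 (51.5), Ccl2 (18.1) and Ccl7 (6.77), at Tap2 (33.8), and at Psmb8 (86.2) by the spread of a peak already listed in part with JQ1. H3K27ac was gained at 7 GTPases (random mean 0.639, percentile 100; Tgtp1 at 33.6), at Oas2 (14.9) and Oas3 (11.2) with 2 more antiviral genes, and at Cd274 (16.5), Lgals9 (6.57) and Cd86 (5.59). IRF1 was gained at 16 antiviral genes (random mean 1.48, percentile 100; Ifit1 at 33.2), 12 MHC class I genes (random mean 0.871, percentile 100; Psmb8 and Tap1 at 46.3) and 11 GTPases (random mean 0.753, percentile 100; Gbp2 at 27.9). STAT1 was gained at 7 GTPases (random mean 0.862, percentile 100; Iigp1 at 10.1) and 7 IFN-γ signalling genes (random mean 1.67, percentile 99.95; Socs1 at 5.79, Socs3 at 5.55). Over all genes the net change was 67 for polymerase (398 lost, 465 gained), 190 for H3K27ac (424 and 614), 405 for IRF1 (692 and 1097) and 899 for STAT1 (129 and 1028). It turned to −77 for IRF1 at gene ends and to −41 for STAT1 with lists of equal length. Peaks of the JQ1 list overlapped in the combination made up 31.3% (30.0 to 32.6) for BRD4, 61.9% (61.5 to 62.3) for polymerase, 78.2% (77.7 to 78.7) for H3K27ac, 33.1% (31.1 to 35.0) for IRF1 and 55.0% (51.2 to 58.7) for STAT1.

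Pairs of comparisons that share no immunoprecipitated library, though all AT-3 lists share an input, changed partly the same genes. BRD4 was lost in both JQ1 comparisons from 2785 gene regions among 6181 occupied in both reference libraries. Independent lists would give 2248, and lists matched on fold in both references 2636, so most of the excess went with peak strength. For polymerase 166 were lost in both (11.0 for independent and 62.3 for matched lists) and for H3K27ac 194 (17.5 and 95.7), with no interferon-list gene among either. IRF1 was lost in both comparisons from 68 gene regions (50.6 and 60.5) and STAT1 from 481 (401 and 456). Gains with IFN-γ seen both without and with JQ1 numbered 155 for polymerase (7.84 for independent lists; 17.7 for lists matched on gene length and on polymerase and H3K27ac with DMSO). They numbered 42 for BRD4 (2.77 and 5.70), 208 for H3K27ac (11.4 and 24.6), 908 for IRF1 (61.5 and 132) and 120 for STAT1 (26.1 and 43.0). Among strong peaks alone, such gains numbered 307 for polymerase, 32 for BRD4, 249 for H3K27ac, 790 for IRF1 and 7 for STAT1. Losses in both JQ1 comparisons numbered 192, 1233, 387, 25 and 6 in the same order. None of these values allows for the shared input. Genes of the interferon lists made up 42 of the 908 and 9 of the 42.

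The overlap of transcription factor and BRD4 peaks in the same treatment was far above that of shuffled positions in every library, and lower with JQ1 for IRF1 and MYC. Of IRF1 peaks, 63.3% (61.4 to 65.2) met a BRD4 peak with DMSO and 33.9% (32.0 to 35.9) with JQ1. The shares were 35.1% (33.7 to 36.5) with IFN-γ and 11.9% (10.9 to 13.0) with both. The fall from DMSO to JQ1 was not limited to BRD4. The share of IRF1 peaks with H3K27ac was 64.8% (62.9 to 66.6) with DMSO and 50.2% (48.1 to 52.2) with JQ1. That with polymerase was 65.1% (63.2 to 67.0) and 51.5% (49.5 to 53.6). With IFN-γ the share with H3K27ac was 41.1% (39.7 to 42.5), and with both agents 39.6% (38.0 to 41.2). That with polymerase was 37.3% (35.9 to 38.7) and 33.0% (31.5 to 34.5). Among STAT1 peaks 32.4% (31.3 to 33.6) met BRD4 with DMSO, 53.9% (50.2 to 57.7) of the much shorter JQ1 list did, and 32.4% (30.9 to 33.9) and 29.2% (27.4 to 31.1) with IFN-γ and both. MYC peaks of Eμ-Myc cells met BRD4 at 58.7% (58.1 to 59.4) with DMSO and 23.4% (22.96 to 23.9) with JQ1, and polymerase at 74.8% (74.3 to 75.4) and 61.9% (61.4 to 62.5). Shuffled peaks met a partner at 0.108% to 4.47% on average. They could land anywhere on their chromosome and were not matched to active or mappable sequence. The gap therefore cannot tell specific co-occupancy from peaks that merely share active chromatin or recurrent regions. BRD4 lists were shorter with JQ1 in both cell lines. Among strong peaks the share with BRD4 was 5.57% for IRF1 with both agents and 6.51% for MYC with JQ1. It was 93.8% for STAT1 with DMSO, where 84.2% of the strong peaks lay in recurrent regions, those listed in at least 7 of the 8 IRF1 and STAT1 lists of AT-3 cells.

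In Eμ-Myc cells BRD4 peaks over genes were fewer and weaker with JQ1, while most gene regions with MYC or polymerase still held a peak of it. BRD4 gene regions went from 9599 to 7943, with 3372 lost and 1716 gained, and firm calls were 840 losses against 3 gains, Ttll6 (6.96), Azin2 (6.65) and Nfe2l3 (6.14). Of the 840 firm losses, 834 carried polymerase with DMSO and 833 with JQ1, and 801 and 825 carried MYC. Of all gene regions occupied with DMSO, 94.8% kept polymerase and 99.2% kept MYC with JQ1. Cell cycle and replication genes lost BRD4 at 10 of 20 (random mean 4.34, percentile 99.9), 9 of them firmly, with E2f1 (11.3), the replication clamp gene Pcna (10.9) and Cdk1 (8.36) highest. MHC class I genes lost it at 10 of 17 (random mean 6.18, percentile 97.8; H2-K1 at 6.70, Pdia3 at 6.67, B2m at 6.18). B-lineage genes kept it at all but Vpreb3 (4.44), 1 of 15 (random mean 4.14, percentile 1.96). MYC targets lost 6 of 30 (random mean 5.42, percentile 62.9; Nop58 at 11.8, Fbl at 8.93), and BET-inhibitor-sensitive regulators 4 of 20 (random mean 3.96, percentile 52.7; Il7r at 6.82, Irf4 at 6.74, Brd4 itself at 5.35 and Bcl2l1 at 5.12). Apoptosis regulators went from 15 to 9 (Casp9 at 6.69, Trp53 at 5.96). Outside the lists, firm losses whose peak met none of the JQ1 list were led by Ankrd10 (15.7), Fbxl4 (15.3), the primase gene Prim2 (14.4) and the actin gene Actg1 (13.8). Peaks were fewer (21491 against 28193), shorter (median width 178 bp against 307 bp) and weaker, with 1021 against 7680 of −log10 p at least 10. Of JQ1 peaks, 45.5% (44.9 to 46.2) lay in the DMSO list, and JQ1 kept 27.2% (26.7 to 27.7) of DMSO peaks. Among strong peaks the last share was 12.0% and the net change was −4109 gene regions instead of −1656.

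Polymerase in Eμ-Myc cells went from 12130 to 11844 gene regions (627 lost, 341 gained; 28 and 8 firmly). The lymphoma lists showed polymerase over 17 of 20 B-lineage genes, 30 of 30 MYC targets and 20 of 20 cell cycle genes with both DMSO and JQ1. Any peak in the region counts here. With JQ1, 14 cell cycle genes had less of their length under polymerase peaks and 6 more. Among B-lineage genes 12 had less and 5 more, and among MYC targets 11 had less and 17 more. Checkpoint ligands lost Tnfrsf14 (4.04), Vtcn1 (3.20) and Cd276 (3.03) (random mean 1.32, percentile 94.2). Firm losses whose peak met none of the JQ1 list were led by Sema3d (12.3) and Nipal4 (8.60), and 6 of the 8 firm gains were the edge of a peak also listed with DMSO. JQ1 kept 51.7% (51.5 to 52.0) of DMSO peaks. BRD4 losses with JQ1 in AT-3 and Eμ-Myc cells met at 1208 gene regions, where independent lists would give 967 and lists matched on fold 1177, and polymerase losses at 61 (9.07 and 35.0).

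MYC, the oncogenic transcription factor that drives this lymphoma, gained gene regions with JQ1. The list grew from 21790 to 30532 peaks and from 11019 to 12103 gene regions, with 1174 gained (76 firmly) and 90 lost. The firm losses were Car10 (6.13) and, by the edge of a peak that stayed, Cfap206 (15.7) and Septin4 (9.43); firm gains whose peak met none of the DMSO list were led by Ppp1r11 (9.01), Aars2 (8.68) and Scaper (8.68). All 30 MYC targets carried MYC in both libraries, and cell cycle genes went from 19 to 18, with Mcm5 (4.86) lost. Gains included Tap2 (7.67) and Tapbpl (3.67) of the MHC class I genes, Il7r (5.83), the immediate early gene Fos (6.67), and 5 antiviral genes (random mean 3.37, percentile 84.0; Herc6 at 6.67, Ddx58 and Eif2ak2 at 6.01, Usp18 at 4.03, Rsad2 at 3.18). Silent tissue-specific genes, fixed as a background, went from 3 to 9 of 24 (6 gained, random mean 1.56, percentile 99.9; Gfap at 5.00, Cryaa at 4.67), and epithelial genes from 6 to 11 of 24 (5 gained, random mean 1.37, percentile 99.6; Ehf at 5.34, Elf5 and Epcam at 4.34, Gata3 at 4.00, Cdh1 at 3.34). MYC peaks of the DMSO list were kept at 92.7% (92.3 to 93.0), while 63.7% (63.2 to 64.3) of JQ1 peaks lay in the DMSO list. With lists of equal length the net gain of 1084 gene regions was 217.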

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

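Tests chosen only after the result was seen were those on reads, on the STAT1 threshold and on recurrent regions (listed in at least 7 of the 8 IRF1 and STAT1 lists of AT-3 cells); the tests on an even drop in enrichment and on the detection limit of MYC were written first. Of 24 pairs of the same contrast examined, 4 went in opposite directions, all of them the effect of IFN-γ in AT-3 cells without and with JQ1. Each rests on 1 library per group, and none of these differences was tested. With IFN-γ the number of polymerase peaks in AT-3 cells was higher by 547 without JQ1 (70413 to 70960) and lower with it (61203 to 59038), a change of −2165. Gene regions with polymerase showed −54 without JQ1 (12130 to 12076) and 67 with it (11783 to 11850). STAT1 peaks showed −2571 with IFN-γ without JQ1 (6357 to 3786) and 1569 with it (684 to 2253), and STAT1 gene regions −1248 (3130 to 1882) and 899 (330 to 1229). Among strong peaks the directions were alike: polymerase peaks went from 12881 to 14499 and from 12567 to 12828, STAT1 peaks from 146 to 234 and from 51 to 147, and net gene regions were 199 and 354 for polymerase and 11 and 45 for STAT1. With lists of equal length STAT1 gene regions also went the same way, −144 and −41. At q 0.05, with q values that are in doubt, STAT1 peaks rose in both pairs, from 935 to 1069 and from 205 to 770. In other cases gene regions kept opposite directions. For polymerase they changed by −61 and 87 with lists of equal length, −134 and 47 at gene ends and −54 and 49 with flanks of 2.5 kb. For STAT1 they changed by −585 and 551 at gene ends and −64 and 250 at q 0.05.

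BRD4 lists of AT-3 cells were shorter with JQ1 than without it, at 4803 against 14055 peaks and 2144 against 12384. Fewer reads do not account for the first pair, since the JQ1 library held 1.69 times the reads of the DMSO library; nor are they the whole cause in the second, where the ratio of reads was 0.886 and that of peaks 0.173, since the DMSO library, with fewer reads (9.43 M against 14.3 M), listed 6.56 times (6.26 to 6.86) the peaks of the library with both agents. An even drop in enrichment would keep peaks of similar fold alike. Among strong DMSO peaks compared at similar fold, those near a gene end were kept more often than others by 18.4 percentage points (15.8 to 20.9), at 68.9% against 50.5%. In the pair with IFN-γ the gap was 11.0 (8.19 to 13.7). This argues against an even drop only if equal fold in 1 reference library means equal strength. The gap was not measured in a pair without JQ1, so the test cannot exclude an even drop. Displacement of BRD4 by the inhibitor, which the design names, may account for both pairs, as a hypothesis found and examined on the same data. A difference in the success of single immunoprecipitations stays open, above all if it acts unevenly over sites, because no treatment has a second library.

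The STAT1 list with DMSO was longer than that with IFN-γ, 6357 against 3786 peaks, although IFN-γ activates STAT1. Leaving out the recurrent regions could not decide the question, since by definition nearly all these lists hold them. They took up 351 DMSO peaks and 338 IFN-γ peaks, and without them 6006 and 3448 were left, a ratio of 0.574 (0.551 to 0.599). The lenient p threshold of these lists may account for it in part: at q 0.05 the IFN-γ list was the longer, with a ratio of 1.14 (1.05 to 1.25) and 1069 against 935 peaks, but the q column of these lists is in doubt, since a header line says that q was not calculated. By p alone the DMSO list was the longer at −log10 p of at least 5 (1442 against 1145) and the IFN-γ list at 6 or more (900 against 708). Both tests were chosen after the lists had been seen, and a real loss of weak STAT1 sites with IFN-γ stays open as untested.

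More MYC peaks were listed in Eμ-Myc cells with JQ1 than with DMSO, 30532 against 21790. More reads are argued against, as the ratio of reads was 0.950. A lower detection limit in the JQ1 library cannot be told apart from wider MYC binding: of the strongest JQ1 peaks, as many as the DMSO list holds, 80.3% lay in the DMSO list, between the bounds of 80% and 90% set for either reading. Of the 11070 JQ1 peaks outside the DMSO list, 415 (3.75%) were strong, and their median fold was 4.34 against 5.82 for the whole JQ1 list.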

How the results depend on the processing

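Tests chosen only after the data were seen were those with the STAT1 lists at q 0.05, with gene ends alone and without recurrent regions, those listed in at least 7 of the 8 IRF1 and STAT1 lists of AT-3 cells. Of 907 values recomputed, 475 stayed within their counting interval or within 1.5 times, 404 moved beyond that without a change of sign, and 28 turned. Flanks of 2.5 kb kept the direction of all 117 list changes and turned no value. Gene ends kept the direction of 115 of the 117, the strict threshold 87 and equal lengths 86. No paired analysis was possible because each group had 1 library. Depth did not order the STAT1 lists: the shortest, 684 peaks with JQ1, came from 16.0 M tags and the longest, 6357 with DMSO, from 12.2 M, and no list was called again at equal depth. The recurrent regions made up 84.2% of strict STAT1 peaks with DMSO and 70.5% with IFN-γ. Motifs were not run. Values follow for each setting, with the value as reported in brackets; "both" is JQ1 plus IFN-γ.

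With peaks of −log10 q (p where no q exists) of at least 10 alone, lists were shorter by construction; beyond that the cause was not tested. Shared peaks, as a percentage of the reference list, came to, for JQ1 against DMSO: polymerase 77.5% (57.2%), BRD4 25.4% (29.4%), H3K27ac 80.1% (81.1%), IRF1 66.3% (63.1%) and STAT1 34.2% (6.04%). For IFN-γ against DMSO: polymerase 80.7% (62.7%), BRD4 54.7% (60.1%), H3K27ac 88.8% (80.3%), IRF1 48.9% (43.5%) and STAT1 69.2% (14.7%). For both against IFN-γ: polymerase 72.6% (54.9%), H3K27ac 81.5%, IRF1 75.1% (70.3%) and STAT1 44.9% (21.6%). For both against JQ1: polymerase 79.6% (61.9%), H3K27ac 88.0% (78.2%), IRF1 40.0% (33.1%) and STAT1 100.0% (55.0%). For JQ1 against DMSO in Eμ-Myc: BRD4 12.0% (27.2%), polymerase 73.5% (51.7%) and MYC 95.2% (92.7%). The net change in gene regions was, for JQ1 against DMSO: polymerase −194 (−347), BRD4 −2412 (−4308), H3K27ac −1019 (−439), IRF1 −224 (−357) and STAT1 −45 (−2800). With IFN-γ against DMSO: polymerase 199 (−54), H3K27ac 204 (111) and STAT1 11 (−1248). With both against IFN-γ: polymerase −39 (−226), BRD4 −2462 (−5601), H3K27ac −673 (−360), IRF1 −246 (−445) and STAT1 −11 (−653). With both against JQ1: polymerase 354 (67), BRD4 −660 (−1970), H3K27ac 550 (190) and STAT1 45 (899). With JQ1 against DMSO in Eμ-Myc: BRD4 −4109 (−1656). Net changes of lists that turned were, for STAT1 with both against IFN-γ: epithelial genes −1 (3). Peaks at Cd274 and 20 kb either side numbered AT-3 BRD4 1 with IFN-γ (3) and 0 with both (1), AT-3 H3K27ac 3 with IFN-γ (6) and 2 with both (6), AT-3 polymerase 0 with DMSO (2), 1 with IFN-γ (12), 0 with JQ1 (1) and 4 with both (20), Eμ-Myc BRD4 0 with DMSO (1) and 0 with JQ1 (2), Eμ-Myc MYC 1 with DMSO (4) and 3 with JQ1 (7), Eμ-Myc polymerase 1 with DMSO (4). Peaks meeting a BRD4 peak made up for IRF1 43.6% with DMSO (63.3%), 20.5% with JQ1 (33.9%), 21.4% with IFN-γ (35.1%) and 5.57% with both (11.9%), for STAT1 93.8% with DMSO (32.4%), 96.1% with JQ1 (53.9%), 57.7% with IFN-γ (32.4%) and 46.3% with both (29.2%), for MYC 45.1% with DMSO (58.7%) and 6.51% with JQ1 (23.4%). Gains with IFN-γ seen without and with JQ1 numbered 307 for polymerase (155) and 7 for STAT1 (120). Losses with JQ1 seen in both pairs numbered 1233 for BRD4 (2785), 387 for H3K27ac (194), 25 for IRF1 (68) and 6 for STAT1 (481).

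With an overlap of 50% of the shorter peak required, shares go down by construction. Shared peaks, as a percentage of the reference list, came to, for JQ1 against DMSO: polymerase 50.2% (57.2%), BRD4 28.4% (29.4%) and H3K27ac 79.1% (81.1%). For IFN-γ against DMSO: polymerase 55.1% (62.7%), BRD4 57.4% (60.1%), H3K27ac 78.7% (80.3%) and STAT1 13.3% (14.7%). For both against IFN-γ: polymerase 48.1% (54.9%), H3K27ac 77.7% and STAT1 20.1% (21.6%). For both against JQ1: polymerase 54.1% (61.9%) and H3K27ac 75.7% (78.2%). For JQ1 against DMSO in Eμ-Myc: BRD4 25.2% (27.2%), polymerase 44.6% (51.7%) and MYC 89.6% (92.7%). Peaks meeting a BRD4 peak made up for IRF1 58.8% with DMSO (63.3%), 32.5% with IFN-γ (35.1%) and 10.6% with both (11.9%), for STAT1 30.5% with DMSO (32.4%) and 30.9% with IFN-γ (32.4%), for MYC 49.1% with DMSO (58.7%) and 20.8% with JQ1 (23.4%).

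With both lists trimmed to the length of the shorter by score, counts of genes come closer by construction; other causes were not tested, and for each turn the cause was not tested. Shared peaks, as a percentage of the reference list, came to, for JQ1 against DMSO: polymerase 60.8% (57.2%), BRD4 60.6% (29.4%), H3K27ac 78.4% (81.1%), IRF1 67.6% (63.1%) and STAT1 41.96% (6.04%). For IFN-γ against DMSO: BRD4 63.9% (60.1%), H3K27ac 77.0% (80.3%), IRF1 23.8% (43.5%) and STAT1 21.7% (14.7%). For both against IFN-γ: polymerase 59.8% (54.9%), BRD4 53.8% (13.8%), H3K27ac 78.9%, IRF1 81.6% (70.3%) and STAT1 32.5% (21.6%). For both against JQ1: polymerase 62.7% (61.9%), BRD4 54.3% (31.3%), H3K27ac 76.3% (78.2%), IRF1 20.9% (33.1%) and STAT1 46.9% (55.0%). For JQ1 against DMSO in Eμ-Myc: BRD4 33.4% (27.2%), polymerase 56.6% (51.7%) and MYC 85.6% (92.7%). The net change in gene regions was, for JQ1 against DMSO: polymerase −224 (−347), BRD4 −83 (−4308), IRF1 −217 (−357) and STAT1 2 (−2800). With IFN-γ against DMSO: BRD4 −166 (−677), H3K27ac −38 (111), IRF1 −416 (493) and STAT1 −144 (−1248). With both against IFN-γ: polymerase −47 (−226), BRD4 −290 (−5601), IRF1 −10 (−445) and STAT1 161 (−653). With both against JQ1: BRD4 −200 (−1970), H3K27ac 96 (190), IRF1 −174 (405) and STAT1 −41 (899). With JQ1 against DMSO in Eμ-Myc: BRD4 −782 (−1656), polymerase −108 (−286) and MYC 217 (1084). Net changes of lists that turned were, for BRD4 with JQ1 against DMSO: antiviral genes 2 (−10), apoptosis regulators 1 (−5), housekeeping genes 1 (−3), MHC class I genes 1 (−6) and NF-κB genes 1 (−3). For BRD4 with both against IFN-γ: epithelial genes 3 (−11), immediate early genes 4 (−3), MYC targets 2 (−17) and NF-κB genes 1 (−4). For BRD4 with both against JQ1: MYC targets 3 (−4). For IRF1 with both against IFN-γ: core histones 1 (−4). For STAT1 with JQ1 against DMSO: BET-inhibitor-sensitive regulators 1 (−3), housekeeping genes 2 (−5) and MHC class I genes 1 (−3). For STAT1 with both against JQ1: housekeeping genes −2 (6).

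With only peaks within 1 kb of a gene end counted, peaks inside long genes no longer counted, by construction; the cause was not tested. The net change in gene regions was, for JQ1 against DMSO: STAT1 −1393 (−2800). With IFN-γ against DMSO: polymerase −134 (−54), H3K27ac −34 (111), IRF1 −160 (493) and STAT1 −585 (−1248). With both against IFN-γ: IRF1 −216 (−445) and STAT1 −257 (−653). With both against JQ1: H3K27ac 115 (190), IRF1 −77 (405) and STAT1 551 (899). With JQ1 against DMSO in Eμ-Myc: BRD4 −3243 (−1656).

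With STAT1 lists at q 0.05, lists were shorter by construction; beyond that the cause was not tested. Shared peaks, as a percentage of the reference list, came to, for JQ1 against DMSO: STAT1 20.6% (6.04%). For IFN-γ against DMSO: STAT1 48.0% (14.7%). For both against IFN-γ: STAT1 44.6% (21.6%). For both against JQ1: STAT1 93.2% (55.0%). The net change in gene regions was, for JQ1 against DMSO: STAT1 −382 (−2800). With IFN-γ against DMSO: STAT1 −64 (−1248). With both against IFN-γ: STAT1 −68 (−653). With both against JQ1: STAT1 250 (899). Net changes of lists that turned were, for STAT1 with both against IFN-γ: epithelial genes −1 (3).

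Without the recurrent regions, peaks in them were removed by construction. Nearly all IRF1 and STAT1 lists hold these regions, so the shares of IRF1 and STAT1 go down by construction too. Beyond that the cause was not tested. Shared peaks, as a percentage of the reference list, came to, for JQ1 against DMSO: BRD4 27.9% (29.4%), IRF1 57.6% (63.1%) and STAT1 2.46% (6.04%). For IFN-γ against DMSO: BRD4 59.2% (60.1%), IRF1 35.7% (43.5%) and STAT1 9.99% (14.7%). For both against IFN-γ: BRD4 12.7% (13.8%), IRF1 68.5% (70.3%) and STAT1 14.2% (21.6%). For both against JQ1: BRD4 29.5% (31.3%), IRF1 22.4% (33.1%) and STAT1 31.7% (55.0%).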

Other observations

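The measures in this part were chosen only after the results were seen, and so were the genes named in it; none of its tests was planned. RNA polymerase II covered less of the antiviral genes with JQ1, even where a peak remained. Antiviral genes, 24 with polymerase in all 4 AT-3 lists, had a median of 19.9% of their length under polymerase peaks with DMSO and 9.61% with JQ1 (21 genes lower, 2 higher), and 94.8% with IFN-γ and 57.5% with both agents (19 lower, 0 higher). The median change gene by gene was smaller, −8.42 percentage points with JQ1 against DMSO and −16.6 with both against IFN-γ. For all 10719 genes with polymerase throughout, the medians were 12.3%, 10.7%, 12.0% and 9.76% with DMSO, JQ1, IFN-γ and both. Ifit3, whose product restrains viral translation and growth, was covered to 29.1% with DMSO and 4.26% with JQ1, and to 100% with IFN-γ, with or without JQ1. The GTPases, 9 genes, stood at 9.93% with DMSO and 4.77% with JQ1 (9 lower, 0 higher), and the MHC class I genes, 15, at 63.9% and 56.8% (11 lower, 1 higher). With IFN-γ and with both agents the medians of these lists sat at the ceiling of 100%, which hides any drop; gene by gene, 3 GTPases were lower with both agents and 0 higher, and 4 MHC class I genes lower and 2 higher. Chemokines and cytokines, also 9, stood at 62.5%, 38.8%, 92.9% and 49.3% with DMSO, JQ1, IFN-γ and both. Gene by gene their median change with JQ1 against DMSO was only −0.529 percentage points (6 lower, 1 higher), against −0.214 over all genes. With both agents against IFN-γ it was −7.57 (6 lower, 0 higher), against −0.440 over all genes. The IFN-γ signalling genes, 19, differed from these lists, at 10.3%, 11.8%, 94.6% and 83.5% with DMSO, JQ1, IFN-γ and both. Gene by gene their median change with JQ1 against DMSO was −0.159 percentage points (10 lower, 8 higher). With both agents against IFN-γ it was 0 (9 lower, 5 higher). Cd274 was covered to 1.86%, 0%, 90.1% and 57.5% in the same order of treatments. MYC targets, many of them factors of ribosome production, went from 72.9% with DMSO to 33.0% with JQ1 (19 lower, 5 higher), and from 90.8% with IFN-γ to 57.5% with both (22 lower, 2 higher). Their median change gene by gene was smaller, −5.92 and −6.24 percentage points. In Eμ-Myc cells the B-lineage genes went from 50.2% to 9.77% with JQ1 (12 lower, 5 higher), with a median change gene by gene of −9.76 percentage points. The B-cell regulator Ebf1 went from 38.9% to 1.36% and Pax5 from 77.5% to 9.38%, while Cd79b, part of the B-cell receptor, had 62.1% and 76.4%. Cell cycle and replication genes of the lymphoma line, 20, had medians of 45.2% with DMSO and 41.4% with JQ1 (14 lower, 6 higher). Their median change gene by gene was larger, −14.0 percentage points, against −0.129 over all genes. MYC targets of the lymphoma line showed no such drop (56.9% and 67.2%; 11 lower, 17 higher).

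The strongest IRF1 sites gained with IFN-γ mostly lay away from gene ends, and more of them carried BRD4 with IFN-γ alone than with DMSO or with both agents. Of 342 such peaks (fold 28.8 to 122), 39.2% lay in gene regions and 5.56% near a gene end. BRD4 overlapped 2.34% of them with DMSO, 59.6% with IFN-γ and 7.89% with both agents. H3K27ac overlapped 4.39%, 39.5% and 45.9%, and polymerase 5.26%, 19.6% and 22.5%, and IRF1 itself stayed at all of them when JQ1 was added. Over all 3427 peaks gained, 25.4% met BRD4 with IFN-γ and 71.5% kept IRF1 with both agents, and of the 343 weakest 29.4% kept it. BRD4 overlapped 22.4% of these weakest peaks with DMSO, 33.5% with IFN-γ and 12.0% with both agents. BRD4 was kept at all 4 AT-3 treatments over 1296 gene regions. Histone genes led these by fold with both agents, H1f3 at 35.5, H2ac20 at 34.2 and H2ac23 at 29.4, with the interferon genes Irf1 at 24.4 and Irgm1 at 20.3 among the highest. Transfer RNA genes, transcribed by RNA polymerase III, kept a BRD4 peak with JQ1 in AT-3 cells at 85.3% (79.8 to 89.5) of the 204 that carried it, against 43.5% of gene regions. With JQ1 added to IFN-γ they kept it at 60.0% (53.2 to 66.5), against 21.0% of gene regions. In Eμ-Myc cells they kept it at 45.8% (37.0 to 54.7), against 64.9% of gene regions. These shares were not matched on fold, and transfer RNA genes close together can share a peak, which the intervals do not allow for. Other antibodies were listed at these genes too: of 408, 65.4% carried IRF1, 50.5% STAT1, 43.6% H3K27ac and 50% BRD4 with DMSO, and IRF1 was kept at 98.1% (95.7 to 99.2) with JQ1.

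A set of 320 narrow regions, with a median width of 523 bp, was listed in at least 7 of the 8 IRF1 and STAT1 lists of AT-3 cells; 107 lay within 1 kb of a transfer RNA gene and 28 on the Y chromosome. They made up 84.2% of strong STAT1 peaks with DMSO, 96.1% with JQ1, 70.5% with IFN-γ and 89.1% with both, and 6.04%, 17.1%, 6.27% and 20.2% of strong BRD4 peaks.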
